A study of Drosophila melanogaster with 4 samples.

How the data were processed

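RNA was taken from eye-antennal imaginal discs of *Drosophila melanogaster* larvae at the wandering stage of the third instar. RNA sequencing libraries came from the wild-type strains Canton S and RAL-208, with 1 library each, and from the glass mutant gl[60j], with 2 libraries. The series' design text counts both wild-type strains as biological replicates and both mutant libraries as technical replicates. Libraries were made with an Illumina TruSeq kit, per the labels' protocols. CASAVA 1.8, TopHat2 2.0, HTSeq and the genome build dm3 are named per the submitters' processing notes, without the role of each. The mode of counting, the use of strand and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, cannot be told apart with certainty.

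The values deposited by the authors are whole-number read counts per FlyBase gene, 1 table per library, without normalization. Each table ends with summary lines of the counter, which were left out of library sizes and tests. Reads assigned to genes made up 76.7% of the counted total in Canton S, 74.4% in RAL-208, 74.7% in the first mutant library and 76.3% in the second. Reads without a unique alignment made up 15.9%, 17.0%, 18.9% and 17.1% in the same order. Reads outside any gene made up 6.04%, 7.16%, 5.04% and 5.18%, and ambiguous reads 1.40%, 1.38%, 1.35% and 1.44%. The tables hold 14885 genes, of which 13746 had a symbol in the reference gene table of assembly BDGP6, matched on the FlyBase identifier, and 1139 stay without one. Because that assembly is not dm3, no coordinates are given, and the reference served for names and gene order alone.

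Gene reads numbered 12118170 in Canton S, 11805345 in RAL-208, 11292175 in the first mutant library and 27044633 in the second. A floor of 3 reads corresponds to 0.248, 0.254, 0.266 and 0.111 CPM (reads scaled to the library's total) in these libraries and to 0.0783 CPM over both mutant libraries together. Where a gene had 0 reads in a group, its fold is a lower bound against that floor. Where it had 1 to 3 reads, the ratio of pooled reads is given with an exact 95% interval from the binomial distribution. Reads are not independent molecules, so these intervals and floors cover counting error only.

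The comparison of genotypes used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, filtering by filterByExpr at its default minimum count of 10, and Benjamini-Hochberg adjustment at 0.05. The mutant libraries were summed to 1 sample, which leaves 1 residual degree of freedom, from the spread between the wild-type strains. The lone mutant sample is thereby assumed to vary like the wild types. This fit is called the fit with summed mutant libraries, and an alternative that enters them as separate samples, with 2 residual degrees of freedom, is called the fit of 4 libraries. The p-values of the latter are too small, since part of its spread is technical, and its calls serve to describe and rank genes. The filter left 9059 genes, of which 691 have no symbol. The TMM factors were 1.01 for Canton S, 1.02 for RAL-208 and 0.966 for the summed mutant. Apart from bounds and pooled ratios, folds between genotypes are ratios of mean CPM without TMM scaling, whereas log2 fold changes are fitted with it. These scales can differ, as for spi, at 0.986 of wild type by CPM but a fitted log2 fold change of 0.051. The common dispersion was 0.0627, a coefficient of variation of 25.0%, and the prior degrees of freedom were 2.53 with summed mutant libraries and 2.42 with 4 libraries. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same 3 columns.

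A set of 22 gene lists was written before the data were examined, namely photoreceptor fate, phototransduction, neuron and synapse, cone and pigment cells, retinal determination, furrow signalling, Enhancer of split complex, EGFR pathway, antennal disc, cell cycle, apoptosis and stress, glia, neuroblast, fat body, salivary gland, muscle, haemocyte, trachea, ecdysone response, sex, detoxification and ribosomal protein. Apart from the ribosomal list, taken by symbol, they hold 347 written entries, of which 31 matched no symbol and are not analysed here. Their genes may still stand in the tables among those without a symbol. They include 5 of the 19 furrow signalling entries, among them wg and Dl. The gene lz stands in the photoreceptor fate and haemocyte lists, and rho, ru and spi stand in the photoreceptor fate and EGFR pathway lists. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists, and again with an estimated correlation and with fry. The estimated correlation came from 1 residual degree of freedom, and the smallest unadjusted camera p of any list with it was 0.118. The p rose also where the estimate was negative, among lists passing at the preset value for fat body (-0.14), cone and pigment cells (-0.11) and glia (-0.077). In the other passing lists the estimate lay above 0.01, from 0.011 for the Enhancer of split complex to 0.39 for haemocyte. It was 0.38 for photoreceptor fate and 0.29 for neuron and synapse. Misses with an estimated correlation thus decide nothing about correlation between genes, and the preset value is not shown to hold. Another 3 lists, for the central nervous system, the ring gland and the larval and adult cuticle, were written after the data had been seen and were not tested with camera.

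The tests, their design, the lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where another origin is stated. The rule takes gl, then the 12 largest falls and 8 largest rises among genes passing the test with at least 10 CPM in the higher group and no overlap between genotypes. Where fewer than 5 genes pass in a direction, it takes those with the smallest p up to 5, which are said not to pass. It adds up to 4 passing members of each list by smallest p, or the 2 with the highest mean CPM where none passes, and the 5 largest ratios in each direction between the wild-type strains. The same rule was then applied to the fit of 4 libraries and to the added lists, a step chosen after the data had been seen. The strains were compared as the log2 ratio of CPM plus 1, without a replicate check. The mutant libraries were compared gene by gene with a chi-square test of their counts, for genes with an expected count of at least 5, which treats reads as independent.

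The procedure was tested on simulated counts for the 9059 genes with the real means and library sizes, in 10 runs with 200 changed genes each. With dispersions drawn near those estimated per gene, the fit with summed mutant libraries recovered 29.0% of 2-fold, 71.3% of 4-fold and 87.1% of 8-fold changes, with 36.4 false calls per run. The median prior degrees of freedom of these runs, 43.7, lay far from the real 2.53. A simulation with a wider spread of dispersions, added after that was seen, gave 2.98, but its median common dispersion of 0.172 lay above the real 0.0627. There the fit with summed mutant libraries made 0 calls at any size of change, as did limma-voom, although 5.14% of unchanged genes had an unadjusted p under 0.05. The fit of 4 libraries recovered 25.1%, 58.1% and 71.5% of the 2-fold, 4-fold and 8-fold changes with 207.2 false calls per run, and DESeq2 recovered 9.10%, 59.9% and 78.5% with 155.8 false calls per run. The same wide simulation put 24.4% of unchanged genes at an unadjusted p under 0.05 in the fit of 4 libraries. The wide dispersions were then scaled down, again after the results had been seen, to a median common dispersion of 0.0637 with 3.28 prior degrees of freedom, the nearest to the real values. On these data the fit with summed mutant libraries recovered 0.597% of 2-fold, 27.8% of 4-fold and 53.2% of 8-fold changes with 5.80 false calls per run. The fit of 4 libraries recovered 51.0%, 78.8% and 88.0% with 219.9 false calls per run, and DESeq2 31.6%, 76.0% and 87.9% with 96.2. In all simulations the mutant libraries differed by counting noise alone, which is less than in the real pair. A list of 20 genes changed 1.5-fold was called by camera in 8 of 10 wide runs and in 10 of 10 scaled ones, and at most 1 of 200 unchanged lists was called in any simulation. The simulated lists were random genes that varied independently. They therefore do not show how often camera calls an unchanged list whose genes vary together.

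Alternatives to the scaling, the filter, the tool, the handling of the mutant libraries, the threshold and the set of libraries were run, with their effect given in the closing section.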

Results

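The data comprise RNA read counts per gene from eye-antennal imaginal discs, the larval tissue that forms the adult eye and antenna. Discs of the wild-type strains Canton S and RAL-208 were each sequenced once, giving 2 biological replicates, and discs of the glass mutant gl[60j] were sequenced as 2 technical replicates. Gene reads ranged from 11292175 in the first mutant library to 27044633 in the second, with 12118170 in Canton S and 11805345 in RAL-208. The 10 most abundant genes held between 5.80% and 6.40% of the reads of each library. The mutant stock's genetic background is not separated from its genotype in this design.

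The first comparison set the glass mutant against wild type, which addresses the genes that depend on Glass, a zinc finger transcription factor needed for photoreceptor differentiation. The gl transcript itself (FBgn0004618) was present in every library, at 299 CPM in Canton S, 235 in RAL-208, and 105 and 108 in the mutant libraries, which is 2.51-fold lower in the mutant. Among genes of photoreceptor function, inaC, the eye protein kinase C of the phototransduction cascade, was at 36.2 and 33.0 CPM in Canton S and RAL-208 and had 3 reads over both mutant libraries, a ratio of 443 (95% interval 151 to 2152). Of 8 tested fat body genes, 5 were called lower by the fit of 4 libraries, among them the larval storage protein genes Lsp1beta (113-fold) and Lsp1gamma, at 3841 and 4944 CPM in the wild types and 56.7 and 57.7 in the mutant. In the other direction, the ecdysone-inducible gene ImpE1 was 2.78-fold higher in the mutant, at 1518 and 1502 CPM against 584 and 504. The fit of 4 libraries placed 1025 genes lower and 729 higher in the mutant, at an adjusted p under 0.05 in edgeR. That fit enters technical replicates of the same mutant sample as separate samples, so its p-values are too small. Its calls, those of the fat body genes included, only describe and rank genes. The fit with summed mutant libraries called 0 of 9059 genes.

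With summed mutant libraries, edgeR's quasi-likelihood test called 0 of 9059 genes, with 923 lower and 583 higher at an unadjusted p under 0.05 and a smallest adjusted p of 0.182. On the same columns limma-voom called 0 genes (1055 lower and 748 higher at an unadjusted p under 0.05), and DESeq2 called 388 lower and 152 higher, of which 513 were also called in the same direction by the fit of 4 libraries. Independently of any test, 510 genes were at least 2-fold lower in both mutant libraries than in both wild-type libraries and 97 at least 2-fold higher, on the scale of CPM plus 1. For gl the log2 fold change was -1.25 (SE 0.20), with an adjusted p of 0.209 in edgeR with summed mutant libraries, 0.0143 in the fit of 4 libraries and 4.09e-06 in DESeq2. The mutant libraries are technical replicates of 1 sample, and the fit of 4 libraries gives 0 calls without either of them, but 2678 lower and 2671 higher without Canton S, and 2195 and 2111 without RAL-208. In simulated data with a common dispersion of 0.0637 (0.0627 in the real data) and 3.28 prior degrees of freedom (2.53), the fit with summed mutant libraries recovered 53.2% of 8-fold changes with 5.80 false calls per run. The fit of 4 libraries recovered 88.0% of them there, with 219.9 false calls per run, and DESeq2 87.9% with 96.2. Where no gene was changed, DESeq2 made 78.6 calls per run, the fit of 4 libraries 36.8 and the summed fit 0. DESeq2 and the fit of 4 libraries use the same counts, so their overlap is not an independent check. The simulated mutant libraries differed by counting noise alone. In them 5.08% of genes had an unadjusted chi-square p under 0.05, against 13.8% in the real pair. The recovery and false calls of the fit of 4 libraries may thus not carry over to the real data.

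**Figure D1:**
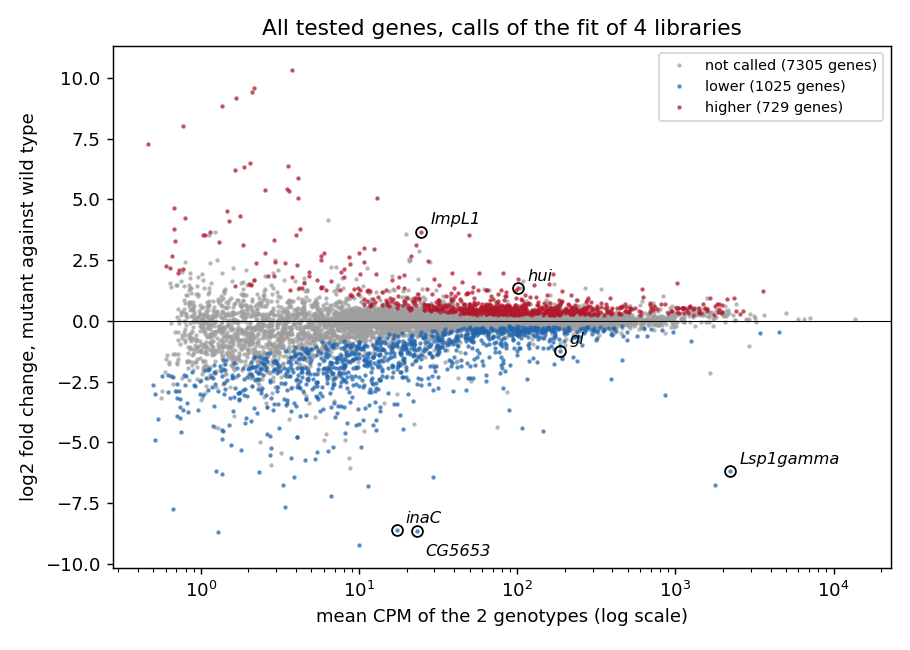
Log2 fold change of the mutant against wild type for the 9059 tested genes (vertical axis, from edgeR with summed mutant libraries) against the mean CPM of both genotypes (horizontal axis, log scale). Colours mark the 1025 genes lower and the 729 higher in the fit of 4 libraries, and circles mark named genes, with gl at -1.25 and Lsp1gamma at -6.18; fitted values of genes with few mutant reads, such as inaC, depend on the prior count.

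The genes with the smallest p-values in the summed fit did not pass its threshold. The lower ones, besides inaC and Lsp1gamma, were CG5653 (51.8 and 40.4 CPM against 0.0886 and 0.111, 462-fold), CG14075 (20.3 and 19.6 CPM, with 1 mutant read) and CG3625 (77.2 and 85.8 against 16.8 and 14.7). The pooled ratio of CG14075 was 764 (95% interval 136.5 to 30250), and its log2 fold change went from -9.21 to -10.86 without the second mutant library. The higher ones were, besides ImpE1, hui (59.2 and 61.6 CPM against 133 and 152), the serpin gene Spn100A (3.80-fold), CG6654 (3.71-fold) and CG15756 (8.19-fold). All 10 had an edgeR adjusted p of 0.182, 0.206 or 0.208 with summed mutant libraries.

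Ranked by fitted fold among genes with at least 10 CPM in the higher genotype, the fit of 4 libraries put several further genes lower in the mutant. Akh, the adipokinetic hormone gene of the corpora cardiaca, was 96.3-fold lower (26.0 and 18.8 CPM against 0.354 and 0.111). Ekar, an eye-enriched glutamate receptor gene, was 85.8-fold lower, and CarT, a carcinine transporter of photoreceptors, was 48.9-fold lower. The larval cuticle gene Lcp3 had 3 mutant reads, a ratio of 167 (95% interval 56.7 to 815), while CG42369 was 44.2-fold (3.38 and 17.2 CPM against 0.354 and 0.111) and CG31313 36.6-fold lower (6.85 and 33.5 against 0.620 and 0.481). Without RAL-208 the log2 fold change of CG42369 went from -5.69 to -4.08, that of CG31313 from -5.18 to -3.63 and that of Lcp3 from -7.21 to -6.25, and without Canton S that of CarT went from -5.40 to -4.75 and those of CG42369 and CG31313 to -6.42 and -5.91. With few mutant reads, the values also depended on the mutant library left out, from -7.49 to -5.89 for Akh, -8.13 to -6.08 for Lcp3 and -6.36 to -4.77 for CG42369. Among the genes placed higher, Ir76a, an ionotropic receptor gene, was at 1.07 and 0.508 CPM in wild type and 25.4 and 25.3 in the mutant, 32.0-fold higher. It was followed by ImpL1 (12.2-fold), CG15522 (11.2-fold, 11.3 and 4.91 CPM against 92.3 and 89.3) and CG15756 (8.19-fold, named above). Next came FBgn0037645 (7.47-fold, 4.04 and 1.02 CPM against 18.4 and 19.4), CG7294 (7.35-fold), CG42326 (6.82-fold) and the gustatory receptor gene Gr61a (6.81-fold). Without Canton S the log2 fold change of Ir76a went from 5.06 to 5.69, that of ImpL1 from 3.67 to 4.38, that of CG15522 from 3.54 to 4.27 and that of FBgn0037645 from 2.98 to 4.29, and that of FBgn0037645 was 2.30 without RAL-208. The edgeR adjusted p of these genes in the fit of 4 libraries lay between 0.00505 for inaC and 0.0401 for CG42369.

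Group by group, no list member passed the summed edgeR fit when adjusted over all genes (1506 of 9059 genes had an unadjusted p under 0.05), so list counts are given as adjusted over the list alone and as called by the fit of 4 libraries over all genes. Photoreceptor fate genes were lower as a set, with a median log2 fold change of -0.49 over 22 members and a camera adjusted p of 0.000152, but an adjusted p of 0.560 with an estimated correlation. The added central nervous system markers were lower too (median -2.75, 15 of 22 called by the fit of 4 libraries), and genes such as elav and scrt are also used by other neurons. Adjusted over the list alone, 10 members were lower and 0 higher with edgeR on summed libraries, and the fit of 4 libraries called 12 lower and 1 higher, against 8 lower and 0 higher in DESeq2. The zinc finger gene scrt was at 173 and 191 CPM in wild type and 54.4 and 55.2 in the mutant, and the Runx factor gene lz was 3.49-fold lower (79.0 and 70.1 against 22.0 and 20.7). The homeobox gene hbn was 5.81-fold lower and svp, a nuclear receptor gene, 1.85-fold lower. Pph13, a homeodomain gene of photoreceptors, was at 3.30 and 1.86 CPM in wild type with 0 reads in the mutant, at least 33.0-fold lower against the floor of 3 reads over both libraries. With Pph13 at that bound the median remained -0.49. The receptor gene sev was at 336 and 287 CPM against 220 and 219, and spi, the EGF ligand gene, was at 334 and 286 against 306 and 305.

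Phototransduction genes had a median of -0.40 over 13 tested members, and the set test gave an adjusted p of 0.0513; the median became -0.13 without RAL-208. Adjusted over the list alone, 2 members were lower with edgeR on summed libraries, and 4 were called lower by the fit of 4 libraries. Besides inaC these were ninaB, an oxygenase gene of chromophore synthesis (37.1-fold lower), Galphaq (221 and 255 CPM against 162 and 165) and Cds (66.2 and 74.6 against 50.7 and 50.7). Without 1 mutant library the log2 fold change of ninaB ran from -7.28 (without the first) to -4.27. The median was unchanged with inaC at the floor.

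Neuron and synapse genes were lower as a set in the mutant, with a median of -0.98 over 23 members and a camera adjusted p of 7.02e-11, which became an adjusted p of 0.560 with an estimated correlation. Adjusted over the list alone, 15 members were lower and 0 higher with edgeR on summed libraries, and the fit of 4 libraries called 15 lower and 0 higher (DESeq2 14 lower). The complexin gene cpx, a regulator of vesicle fusion, was 5.77-fold lower (94.2 and 122 CPM against 19.9 and 17.5). The Alk ligand gene jeb was 6.22-fold lower, the synaptic calcium sensor gene Syt1 3.40-fold and the transcription factor gene onecut 2.79-fold. The calmodulin gene Cam (803 and 963 CPM against 857 and 819) and Appl (646 and 646 against 562 and 555) were not called. They were the most abundant members by mean CPM over both genotypes. In the added list of central nervous system markers, whose genes serve the larval brain and nerve cord, 15 of 22 measured members were called lower by the fit of 4 libraries, and their median was -2.75.

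Cone and pigment cell genes had a median of -1.52, with 10 of 10 tested members below 0 and a camera adjusted p of 2.31e-06. With an estimated correlation, which was negative here (-0.11), the camera adjusted p was again 0.560. The central nervous system markers, at a median of -2.75, were lower beside them, and the member pros (145 and 236 CPM against 59.2 and 62.8) also serves the nervous system. With edgeR on summed libraries 8 were lower adjusted over the list alone, and the fit of 4 libraries called 8 lower. The ommochrome pathway gene cn was 54.7-fold lower (9.82 and 15.2 CPM against 0.0886 and 0.370), and its log2 fold change went from -5.35 to -6.93 without the second mutant library. The pigment transporter gene w was 4.49-fold lower, the cone cell Pax gene sv 2.92-fold and the adhesion gene sns 1.59-fold. The adhesion gene rst was at 403 and 337 CPM against 311 and 297 and the homeobox gene ct at 161 and 182 against 116 and 117.

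Among lists of disc patterning, 2 passed the set test as higher in the mutant, by small amounts. Retinal determination genes had a median of 0.40 over 13 members and a camera adjusted p of 0.00195. The Enhancer of split complex list, which besides E(spl) genes holds Brd, Tom and Ocho, had a median of 0.38 over 14 members. Its camera adjusted p was 0.000103, and both lists had an adjusted p of 0.560 with an estimated correlation. In both lists 0 members passed edgeR with summed libraries adjusted over the list alone, while the fit of 4 libraries called 7 higher in the first list, and 8 higher and 1 lower in the second, and DESeq2 called 1 and 2 higher. The nuclear factor gene dan was 1.58-fold higher, its relative danr was at 116 and 100 CPM against 166 and 159, and the Pax6 genes toy and ey were 1.32-fold and 1.24-fold higher. The abundant members dac (363 and 340 CPM against 417 and 434) and hth (904 and 998 against 1073 and 1056) differed less. Of the Bearded family, Brd was 2.28-fold higher (70.1 and 50.2 CPM against 137 and 137), Tom 1.61-fold, E(spl)m4-BFM 1.42-fold and E(spl)malpha-BFM 1.35-fold. The 1 lower call of the list, named outside the rule, was of the same family. This was E(spl)m6-BFM (5.20 and 6.35 CPM against 2.30 and 1.96, 2.71-fold lower).

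Other lists of the disc did not pass the set test. Furrow signalling genes had a median of 0.12 over 14 members (adjusted p 0.188), with 3 called higher by the fit of 4 libraries, namely N (1.20-fold), ptc (1.13-fold) and Dad (1.12-fold), while ci was at 817 and 948 CPM against 926 and 912. The EGFR pathway list had a median of -0.11 over 18 members (adjusted p 0.277), with 4 called lower and 2 higher. Among them the ligand-processing gene rho was 1.97-fold lower, the feedback inhibitor gene aos 1.49-fold lower, ru 1.35-fold lower and the repressor gene aop 1.26-fold higher, and ed was 1.14-fold higher. In the antennal disc list the median was -0.07 over 10 members while camera's direction was up (adjusted p 0.679), and the median became 0.0062 without RAL-208. Of its members, sob (1.43-fold) and drm (1.37-fold) were called higher and Dll 1.37-fold lower, with bab2 at 181 and 167 CPM against 185 and 178. Cell cycle genes had a median of -0.03 over 24 members (adjusted p 0.660), and 1 member, E2f1, was called, 1.30-fold lower, while the kinase gene polo was at 430 and 432 CPM against 373 and 369. These lists held 0 members past edgeR with summed libraries adjusted over the list alone and, apart from 1 lower member of the EGFR list, 0 calls in DESeq2.

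In the apoptosis and stress list (median 0.08 over 17 members, -0.057 without Canton S, adjusted p 0.537), the small heat shock genes Hsp23 (1599 and 1733 CPM against 3037 and 2999.9) and Hsp27 (1.79-fold) were higher, both also with edgeR on summed libraries adjusted over the list alone. The fit of 4 libraries also placed Hsp68 (2.66-fold), Hsp83 (1.47-fold) and the TNF gene egr (1.39-fold) lower. Ribosomal protein genes were higher as a set, with a median of 0.43 over 81 members, 80 of them above 0, and a camera adjusted p of 8.17e-18 that became an adjusted p of 0.560 with an estimated correlation. With edgeR on summed libraries 0 of them passed adjusted over the list alone, whereas the fit of 4 libraries called 34 higher and DESeq2 31. Among the called members RpL34a and RpL17 were 1.37-fold higher, as was RpS28b, and RpL32 1.36-fold, while the abundant RpS3A was at 2586.5 and 3454 CPM against 3277 and 3292 and RpL3 at 2920.3 and 2687 against 2967.5 and 3336.5. The sex list had a median of -0.03 over 4 members (adjusted p 0.522), with fru called 2.32-fold lower and dsx (70.7 and 76.7 CPM against 66.2 and 67.1) and msl-2 (85.6 and 97.8 against 92.6 and 89.5) not called. Detoxification genes had a median of -0.82 over 9 members (adjusted p 0.104), with Cyp6g1 (6.41-fold, 20.4 and 60.6 CPM against 6.20 and 6.43), Cyp12a4 (6.72-fold) and Cyp6g2 (1.89-fold) called lower and Jheh2 at 337 and 242 CPM against 288 and 282. Without RAL-208 the log2 fold change of Cyp6g1 went from -2.59 to -1.61, and without the second mutant library that of Cyp12a4 from -2.48 to -3.15.

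**Figure D2:**
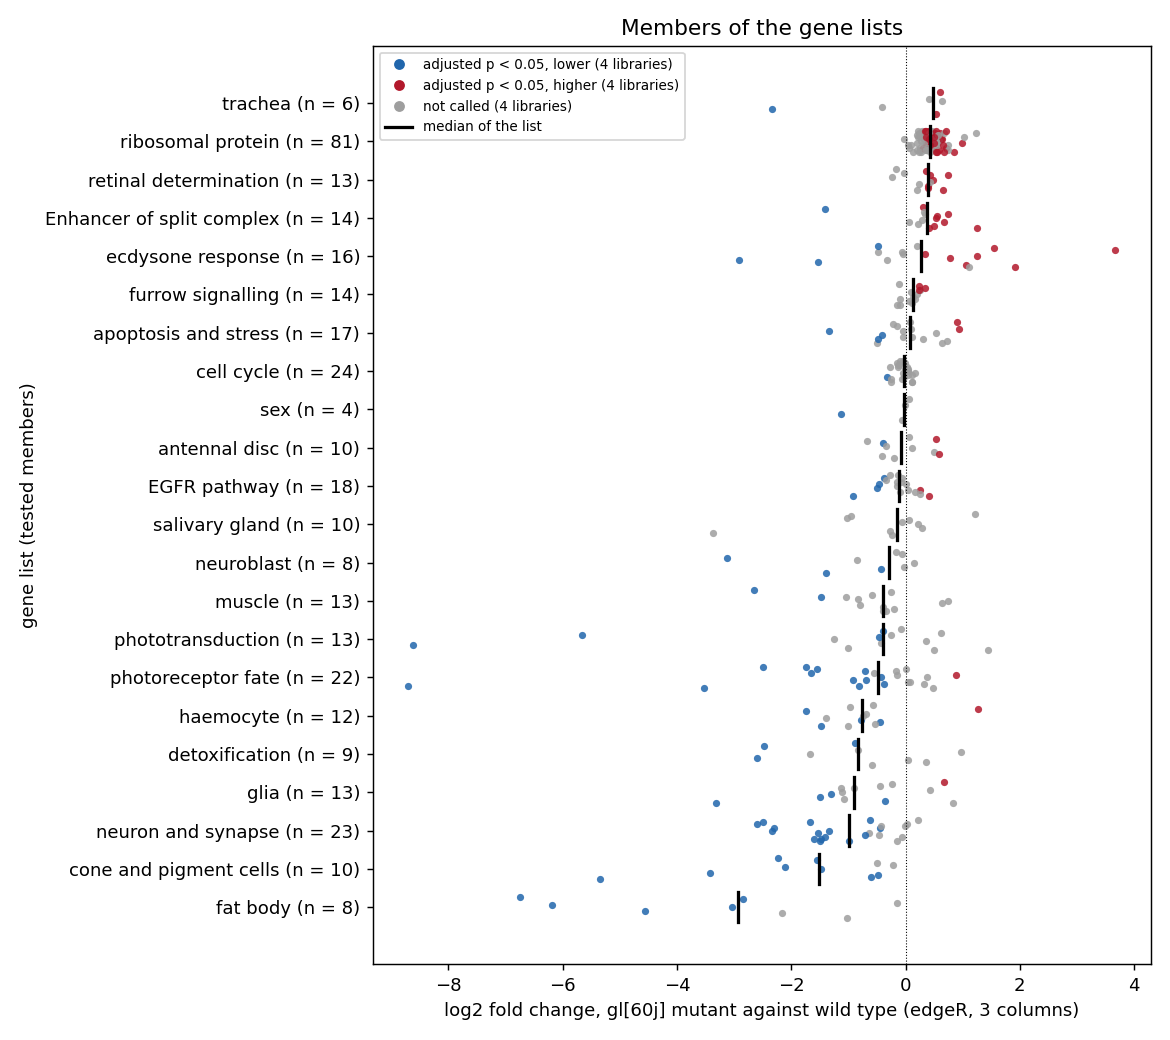
Log2 fold change of the mutant against wild type for the tested members of the 22 lists (points, with the number of members beside each name) and the median of each list (black bars). Colours give the calls of the fit of 4 libraries, and the medians run from -2.94 for the fat body list to 0.48 for the trachea list.

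Ecdysone response genes were higher as a set, with a median of 0.27 over 16 members and a camera adjusted p of 0.0432, but an adjusted p of 0.560 with an estimated correlation and 0.0854 for camera on the 4 libraries, and 0.265 with no filter on low counts. The median became 0.48 without Canton S and 0.11 without RAL-208. With edgeR on summed libraries 5 were higher and 1 lower adjusted over the list alone, and the fit of 4 libraries called 7 higher and 3 lower. Of the called genes with the smallest p, besides ImpE1, ImpE2 was 2.28-fold higher (2405 and 1998 CPM against 5118 and 4906), ImpL1 12.2-fold and ImpL2 1.63-fold. Other called members, named outside the rule after their values were seen, were the nuclear receptor gene Hr3 (3.62-fold), ImpE3 (1.98-fold) and Hr39 (1.22-fold), which were higher, and the 3 lower ones. These were ftz-f1 (25.1 and 32.2 CPM against 10.7 and 8.87, 2.92-fold), Eip74EF (1.44-fold) and Edg91 (9.06-fold), whose log2 fold change of -2.91 became -2.28 without RAL-208 and -3.58 without the second mutant library. Without Canton S that of ImpL1 went from 3.67 to 4.38.

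Markers of other tissues also differed between the genotypes. Fat body genes had a median of -2.94 over 8 members and a camera adjusted p of 0.000103, with an adjusted p of 0.560 with an estimated correlation. Adjusted over the list alone 4 were lower with edgeR on summed libraries, and the fit of 4 libraries called 5 lower. The storage protein gene Lsp1beta was 113-fold lower (2043 and 5065 CPM against 31.9 and 31.1), Lsp1alpha 24.5-fold (448 and 109 against 11.5 and 11.2) and the lipoprotein gene apolpp 8.50-fold. The log2 fold change of Lsp1beta went from -6.75 to -5.96 without RAL-208, and that of Lsp1alpha from -4.55 to -3.19 without Canton S and to -5.24 without RAL-208. The members not called, namely Fbp1, Fbp2 and Lsp2, were higher in the mutant than in RAL-208. The receptor gene Fbp1 was at 7835 CPM in Canton S, 56.8 in RAL-208, and 1894 and 1840 in the mutant, and its log2 fold change of -1.02 (SE 2.51) became 5.11 without Canton S.

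Haemocyte genes were lower as a set (median -0.75 over 12 members, camera adjusted p 0.00375), as were glial genes (median -0.90 over 13 members, 0.0204), both with an adjusted p of 0.560 with an estimated correlation. The central nervous system markers, at a median of -2.75, were lower beside the glial genes. The haemocyte median became -1.05 without Canton S and -0.30 without RAL-208. In each list, 3 members were lower and 1 higher with edgeR on summed libraries adjusted over the list alone, and the fit of 4 libraries called 4 lower and 1 higher. The glutamate transporter gene Eaat1 was 10.9-fold lower, the blood-brain barrier transporter gene Mdr65 2.93-fold and wrapper 2.68-fold, while the innexin gene ogre was 1.51-fold higher and bnb was at 568 and 338 CPM against 787 and 761. The called haemocyte members include lz (3.49-fold lower), which also stands in the photoreceptor fate list. The haemocyte receptor gene NimC1 was 2.83-fold lower, the GATA factor gene srp 1.77-fold lower and the prophenoloxidase gene PPO2 2.29-fold higher. Hml, a marker of mature haemocytes, stood at 149 and 395 CPM against 187 and 175 and the collagen gene Col4a1 at 155 and 393 against 129 and 129, and neither was called.

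Neuroblast genes, also of the central nervous system, had a median of -0.30 over 8 members (adjusted p 0.0513), with the transcription factor genes wor 10.1-fold, ase 2.63-fold and klu 1.40-fold lower in the fit of 4 libraries, brat at 782 and 861 CPM against 711 and 692 and grh at 357 and 342 against 380 and 365. In edgeR with summed libraries 1 neuroblast gene was lower adjusted over the list alone. Muscle genes had a median of -0.40 over 13 members (adjusted p 0.0829), which became -0.67 without Canton S and 0.021 without RAL-208, with the titin gene sls 2.92-fold and Act88F 7.26-fold lower and Act57B at 80.0 and 97.8 CPM against 69.6 and 65.9. The trachea list had a median of 0.48 but a mean of -0.09 over 6 members (adjusted p 0.257, direction up), with serp 1.44-fold and bnl 1.41-fold higher and trh 5.31-fold lower, and verm and pio not called at 1.47-fold and 1.27-fold. Adjusted over the list alone, edgeR with summed libraries gave 1 tracheal gene lower and 1 higher. Salivary gland genes had a median of -0.15 over 10 members, against a camera direction of up (adjusted p 0.927), the median became 0.66 without Canton S, and none was called by edgeR in either fit or by DESeq2. The glue genes Sgs3 (34.9 and 10.3 CPM against 24.0 and 27.3) and Sgs7 (48.5 and 13.9 against 24.9 and 24.7) lay within the range of the wild types.

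The second comparison, between the wild-type strains, describes how far the biological replicates differ, with 1 library each and therefore no replicate check. Fbp1, a fat body receptor gene, was 138-fold higher in Canton S than in RAL-208 (95% counting interval 128 to 149). The mitochondrial genes mt:CoII, by 125-fold (87.3 to 185), mt:ATPase6, by 118-fold (50.2 to 364), and mt:Cyt-b, by 56.9-fold (33.7 to 105), were higher in Canton S too, as was the sodium channel gene ppk13, with 2 reads in RAL-208 and a ratio of 213 (58.7 to 1767). In RAL-208 the immune-induced gene IM33 was higher by 122-fold (52.1 to 378) and FBgn0040813 by 119-fold (83.6 to 175). The ribosomal RNA pseudogene 18SrRNA-Psi:CR41602 had 0 reads in Canton S and 69.7 CPM in RAL-208, at least 282-fold higher, FBgn0085757 at least 279-fold higher, and another gene without a symbol, at 49.9 CPM in RAL-208, at least 201.5-fold higher, against the floor of 3 reads.

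Over the tested genes the median absolute log2 ratio was 0.172 between the strains and 0.216 between the means of both genotypes. At least 2-fold differences numbered 262 genes higher in RAL-208 and 263 higher in Canton S. Spearman's correlation of counts across genes, which are not independent replicates, was 0.977 between the strains. Reads of repeated or near-identical sequences, such as the ribosomal pseudogene and the mitochondrial genes with their nuclear copies, are uncertain in such counts.

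The third comparison, between the mutant libraries, measures technical variation. The median absolute log2 ratio was 0.0680 and Spearman's correlation of counts across genes 0.999, and 8 genes were at least 2-fold apart. A chi-square test of 8905 genes gave an unadjusted p under 0.05 for 13.8% of them, and 292 genes passed after Benjamini-Hochberg adjustment, so the counts of these libraries differed slightly beyond counting noise and are not copies of 1 table.

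**Figure D3:**
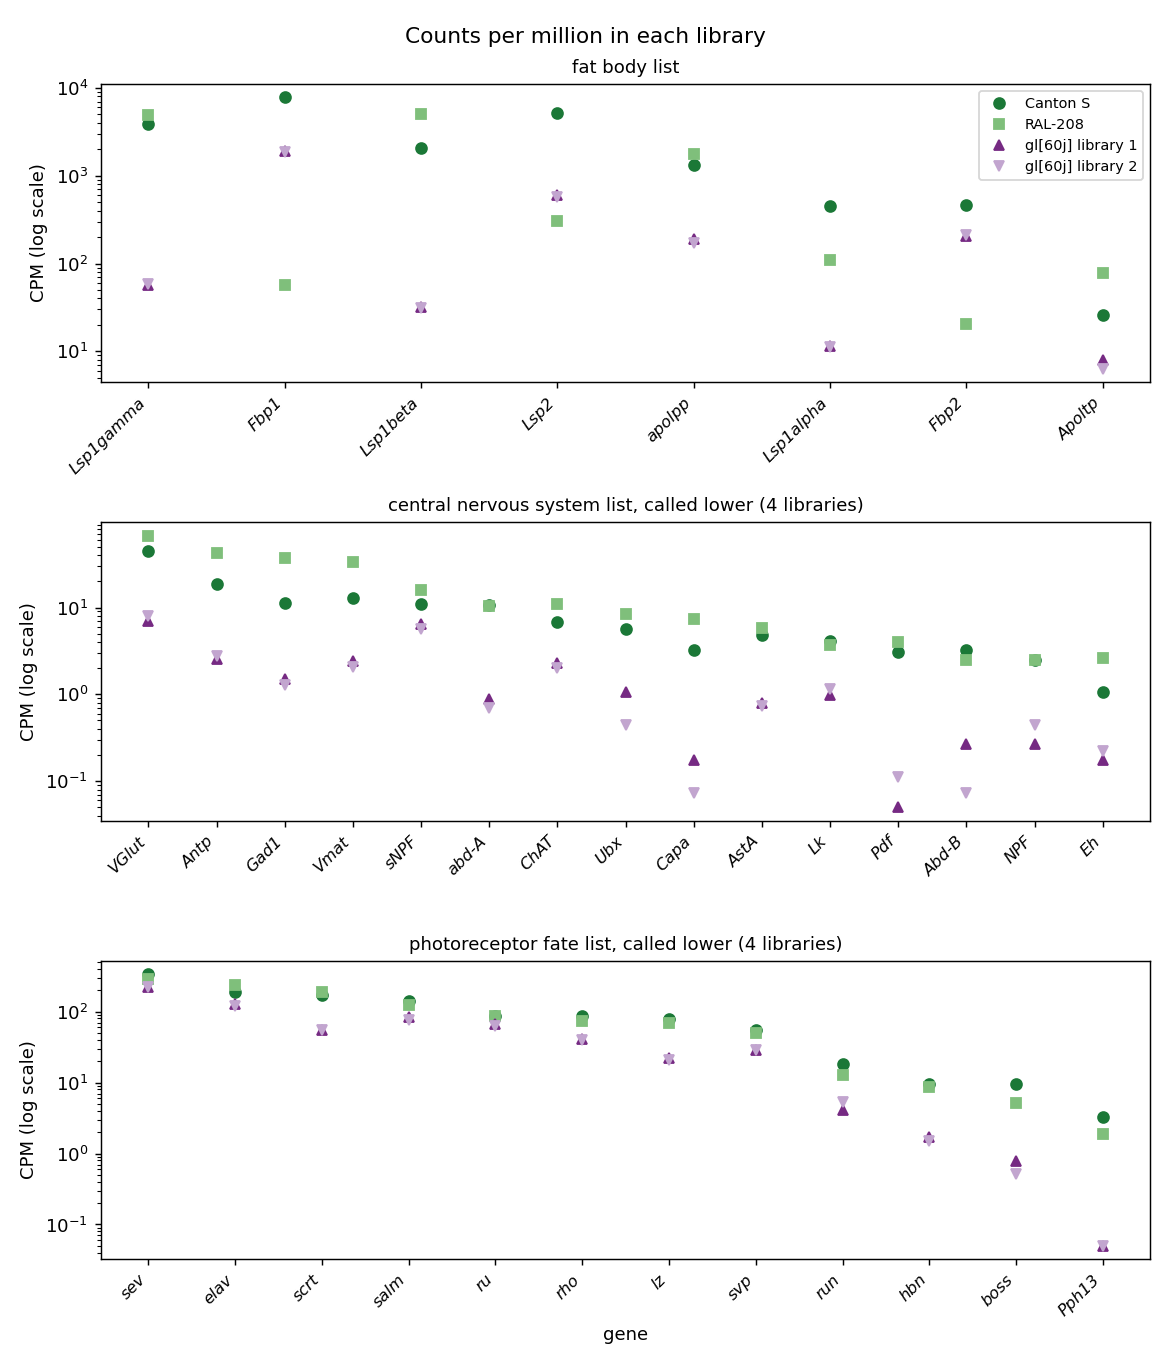
CPM in each of the 4 libraries (log scale) for members of the fat body list, and for members of the added central nervous system list and the photoreceptor fate list called lower by the fit of 4 libraries; a value of 0 is drawn at 0.05 CPM. In Canton S and RAL-208, Fbp1 was at 7835 and 56.8 CPM, apolpp of the same panel at 1329 and 1745, and scrt at 173 and 191. Genes of the lower panels were drawn by a call that favours a small spread between the wild types. The spreads of the panels can therefore not be compared.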

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

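The alternatives to the fit of 4 libraries, and each library left out of it, were chosen after the data had been seen; the others were planned. The count of genes called was 0 in each direction with summed mutant libraries in edgeR under every scaling, filter and threshold tried, and in limma-voom, which was run with TMM and the default filter alone. It was 388 lower and 152 higher with DESeq2, and 1025 lower and 729 higher with the mutant libraries as separate samples. Leaving out 1 library at a time gave between 0 and 2678 lower and between 0 and 2671 higher. The high ends come from leaving out Canton S with the mutant libraries as separate samples, where only technical spread is left; all 1025 lower and 729 higher genes were then called again, in the same direction, as they were without RAL-208. For the fit of 4 libraries the leave-outs also ran from 0 to 2678 lower and from 0 to 2671 higher, the 0 coming from leaving out either mutant library.

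Within the fit of 4 libraries, other choices gave between 802 and 1188 lower and between 499 and 777 higher genes. Library size alone moved the split to 1188 lower and 499 higher, where TMM gave 1025 and 729. With summed mutant libraries it moved the median of all genes from 0.00 to -0.07 and that of the ribosomal list from 0.43 to 0.36. Without the members of the fat body, neuron and synapse, neuroblast, glia, haemocyte, central nervous system and ring gland lists, 969 lower and 714 higher were left. These members are markers and not all transcripts of those tissues. The counts therefore do not measure how many calls carried-over tissue accounts for.

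The log2 fold change of gl was -1.25 with DESeq2 (adjusted p 4.09e-06) and -1.26 with 4 libraries in edgeR (adjusted p 0.0143), past the threshold that the edgeR fit with summed libraries missed; without 1 library it ran from -1.42 to -1.07. Lists lower numbered 6 and lists higher 4, and both were 0 with an estimated correlation and 0 with fry; the other alternatives gave 5 to 8 lower and 3 or 4 higher. The phototransduction list passed camera with no filter (adjusted p 0.0170), with the stricter filter (0.0125) and without the second mutant library (0.0445), and the ecdysone list failed it with no filter (0.265). The strain difference ran from 0.117 to 0.182 and the technical difference from 0.0524 to 0.0721 over their alternatives.

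These directions reversed, each for a gene or list that had not been called. With library size alone, spi became -0.023, msl-2 -0.022 and Jheh2 -0.028. With limma-voom, Fbp1 became 1.55 and Fbp2 1.17. With no filter, Cam became 0.040, and the salivary gland list, at a median of -0.20, changed its camera direction. Leaving out 1 library at a time, the log2 fold change ran from -0.067 to 0.17 for spi, -0.13 to 0.12 for Cam, -2.01 to 5.11 for Fbp1, -1.10 to 3.43 for Fbp2, -3.08 to 1.02 for Lsp2, -0.90 to 0.91 for Sgs7, -0.35 to 1.41 for Sgs3, -1.06 to 0.34 for Hml, -0.036 to 0.15 for msl-2, -0.18 to 0.30 for Jheh2 and -0.0020 to 0.41 for RpS3A. List medians ran from -0.10 to 0.0062 for the antennal disc, -0.057 to 0.12 for apoptosis and stress, -0.47 to 0.66 for the salivary gland and -0.67 to 0.021 for muscle. All these lowest and highest values came from leaving out a wild-type library; Cam also became 0.0076 without the second mutant library.

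For a gene, a limit on movement was set at the standard error of its fitted log2 fold change. For a list it was the standard deviation of its members' log2 fold changes over the square root of their number. Neither limit is a spread between replicates. Further values moved by more than these limits. Without Canton S these were 13 genes, among them Lsp1alpha (-3.19), w (-1.67), Hr3 (2.41), ImpE3 (1.37), ImpL1 (4.38), Ir76a (5.69), CG15522 (4.27) and FBgn0037645 (4.29), and the medians of 5 lists: furrow signalling (0.065), cell cycle (-0.090), muscle (-0.67), haemocyte (-1.05) and ribosomal protein (0.40). Without RAL-208 they were 12 genes, among them CG42369 (-4.08), CG31313 (-3.63), Cyp6g1 (-1.61), Lsp1beta (-5.96), apolpp (-2.82), VGlut (-2.48) and fru (-0.81), and the medians of 3 lists: furrow signalling (0.20), haemocyte (-0.30) and ribosomal protein (0.38). The cause of these movements and reversals was not tested.

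No paired analysis was possible because the wild-type libraries carry no replicate numbers. Depth was at least 11292175 gene reads in each library, where a floor of 3 reads is at most 0.266 CPM.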

Other observations

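All tests below except that of linked variants were chosen after the results had been seen.

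The lists written after the data had been seen add markers of tissues that lie next to the disc. Of 22 measured central nervous system markers, 15 were called lower in the mutant by the fit of 4 libraries and 0 higher, with a median log2 fold change of -2.75, which was the same with Pdf at its bound. The vesicular glutamate transporter gene VGlut, the most abundant of those called, was at 44.8 and 67.1 CPM in Canton S and RAL-208 and at 7.08 and 7.95 in the mutant. The Hox gene abd-A was 13.3-fold lower and the neuropeptide gene AstA 6.86-fold lower, and the circadian neuropeptide gene Pdf had 3 mutant reads, a ratio of 44.9 (95% interval 14.8 to 222), and its log2 fold change went from -5.31 to -8.36 without the second mutant library, which held these reads. These markers were higher in RAL-208 than in Canton S for 16 of 22 genes, with a median difference of 0.53.

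In the ring gland list, of endocrine genes, 2 of 8 measured members were called lower, with a median of -0.19. These were Akh and the ecdysone synthesis gene spok (373 and 313 CPM against 177 and 160, 2.03-fold). In the larval and adult cuticle list 4 of 7 measured members were called lower and 2 higher, with a median of -3.26, also with Lcp3 at its bound. Of these, Lcp2 was 10.2-fold lower, while TwdlE was 2.36-fold and TwdlT 2.48-fold higher.

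Neural and photoreceptor genes were both lower in the mutant. Central nervous system tissue in the wild-type libraries is a candidate explanation for the neural genes, as its markers had a median of -2.75. For the photoreceptor genes it cannot be told apart from a loss of photoreceptors. The 35 tested photoreceptor fate and phototransduction genes had a median RAL-208 to Canton S log2 ratio of -0.169 (percentile 0.04 of 10000 random lists matched on mean expression) and the 22 markers 0.53 (percentile 99.99), but with 1 library per strain a strain difference in the photoreceptor genes could hide a shared source. No gene of the added nervous system list stands in the other lists, but how many of its genes the disc itself or other tissues use was not determined here. The markers were also not chosen to tell brain from nerve cord. Loss of neurons that depend on Glass stays open beside carried-over tissue, since the samples hold no disc with a known content of central nervous system tissue.

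Fat body genes were lower and several ecdysone response genes higher in the mutant, and a smaller amount of fat body of 1 composition was tested as a source of the first. Across 7 abundant fat body genes the log2 ratio of the mutant to Canton S spanned 4.88, and 3 of them were higher in the mutant than in RAL-208. However, the wild types already differed in composition, with RAL-208 to Canton S log2 ratios from -7.08 for Fbp1 to 1.31 for Lsp1beta. With no composition shared even by the wild types, the test cannot decide whether the mutant sample held less fat body. A difference in larval stage was tested for both patterns. The Canton S to RAL-208 ratio went with the mutant's fold change across genes, which are not independent replicates, in the fat body list (r 0.721, exact permutation p 0.0496, adjusted over both lists 0.0496, Spearman's rho 0.667 with p 0.0831, n = 8) and in the ecdysone list (r 0.644, permutation p 0.00711, adjusted 0.0142, rho 0.674 with p 0.00521, n = 16). However, all tested genes share the wild-type libraries and gave r of 0.209, and 10000 random lists of the same sizes gave medians of 0.342 and 0.283. The observed values lay at percentiles 79.4 and 83.95 of those lists, so a stage difference cannot be told apart from other differences between the stocks.

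Variants linked to gl in the mutant stock might add to the genes called. Among the 200 tested genes nearest to gl on arm 3R in the gene order of assembly BDGP6, 42 were called by the fit of 4 libraries (21.0%), against 1529 of 8167 other genes (18.7%). Left out were gl itself and the 691 tested genes without a symbol, of which 182 were called. The odds ratio was 1.15 (95% interval 0.797 to 1.64, Fisher's exact p 0.410). The interval includes both no excess and one of moderate size, and variants elsewhere in the stock's background are not covered by it.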
